A study of Mus musculus with 12 samples.

How the data were processed

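Gene expression was measured on 12 Affymetrix Mouse Genome GeneChip arrays, 3 for each of 4 progenitor populations sorted from the bone marrow of female C57BL/6 mice. Per the labels' protocols, RNA of 80000 cells per population was extracted with Trizol, cleaned on RNeasy Micro columns and labelled with biotin. The labels call the 3 arrays of a population biological replicates. They do not say whether each came from separate animals or pools, so the p-values of probe sets, genes and scores measure only the spread between these arrays. Those of gene lists also rest on how strongly the genes of a list are taken to vary together.

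The authors deposited log2 values for 45037 probe sets, made with GCRMA per the submitters' processing notes. The GCRMA version and the base of the logarithm are not given in the sources used here. The values were read as log2 because GCRMA gives log2 values and 1 probe set spans 10.8 units over the 12 arrays. The median of the 12 values of every probe set lies within 5e-07 of 0. The deposited log2 values are therefore relative to the median array of each probe set, and the absolute signal is lost. The table held 0 control probe sets, so RNA quality from 3' and 5' probe sets was not examined. Array medians ran from -0.0267 to 0.0549.

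The centring changed parts of the plan made before the data were examined. A filter at log2 4 in at least 3 arrays and a stricter filter at log2 6 need absolute signals, so neither was applied and all probe sets were tested. Each gene was represented by its probe set with the largest standard deviation over the 12 arrays, in place of the highest mean. The median range over the arrays was 0.462 log2, and 23009 probe sets had a range under 0.5. Such a flat probe set may be absent or even in all 4 populations, and nothing is said here about its level. GCRMA draws weak signals toward a background, so the size of a fold with 1 group near background is uncertain.

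The annotation paired 34945 probe sets with exactly 1 gene symbol, 932 with several and 9160 with none. Of the 34945, 34741 were found by gene number in a RefSeq table of GRCm38.p6, used for names alone, and 0 symbols needed an update. This gave 18193 genes, 9010 of them with several probe sets. Genes with 1 probe set called higher and another called lower numbered 13 in CD27+ against CD27- CMP, 8 in GMP against MEP, 11 in CD27+ CMP against MEP, 11 in CD27- CMP against GMP and 0 in the other comparisons. None of them is named in the text.

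Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per population, contrasts between populations and empirical Bayes moderation with default settings (prior degrees of freedom 0.992). All 12 arrays entered a single fit, which shares the estimate of spread. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p under 0.05. Counts of probe sets were adjusted over all 45037 probe sets and counts of genes over the 18193 genes. The number of arrays limits the precision: the standard error (SE) of a difference had a median of 0.144 log2 and a 90th percentile of 0.362 log2.

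The genes named in the text follow a rule set before the data were examined. Among genes past the threshold whose 3 and 3 arrays did not overlap, those with the largest log2 difference were taken in each direction: 12 for CD27+ against CD27- CMP, 10 for GMP against MEP, 8 for CD27+ CMP against GMP and for CD27- CMP against MEP, and 4 for the remaining comparisons. For genes highest in a population the 6 with the largest smallest difference were taken. Unnamed gene models were left out. The genes of the sort markers and members of the gene lists could also be named.

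The 18 gene lists were also fixed in advance. They cover erythroid genes, haem synthesis, megakaryocyte and platelet genes, erythro-megakaryocytic transcription factors, neutrophil granule proteins, monocyte and macrophage genes, granulocyte-monocyte transcription factors and receptors, stem cell genes, early lymphoid genes, mature B cell markers, mature T and NK cell markers, mast cell, basophil and eosinophil genes, mitosis, DNA replication, ribosome biogenesis and Myc, interferon response, immediate early and stress genes, and stromal and endothelial markers. Klf1 stands in the erythroid list and in the transcription factor list, and Alas2 stands in the erythroid and haem lists. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, at least 3 measured members and adjustment over the 18 lists, and again with the correlation estimated per list. Counts adjusted over the list alone are given where they differ from those over all genes, or are said to be equal.

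A position score was computed per array as the mean log2 value of genes higher in GMP minus the mean of those higher in MEP. It was rescaled to put the MEP mean at 0 and the GMP mean at 100, and its genes were chosen from the 6 GMP and MEP arrays alone. Scores were compared with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 arrays against 3. The sharing of directions between both main comparisons used a pair of separate fits with no array in common.

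The populations carry the same replicate numbers, and the labels do not say what a number marks. By the rule fixed in advance, numbers pair the arrays where every same-numbered pair deviates from its group means with a correlation over 0.1. The correlations were 0.43, 0.27 and 0.58 for GMP and MEP and 0.57, 0.23 and 0.26 for CD27+ CMP and GMP. The other 4 comparisons did not meet the rule.

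The scripts were tested on simulated data with 100 probe sets changed 2-fold and 100 changed 4-fold in each comparison. The changed probe sets were drawn from those with a residual spread above the median. For CD27+ against CD27- CMP, 32 and 79 of them were recovered, and 8.26% of the calls were probe sets that had not been changed. The figures were 36, 77 and 6.61% for GMP against MEP, 39, 81 and 4.76% for CD27+ CMP against GMP, and 34, 74 and 2.70% for CD27- CMP against MEP. Of simulated lists for CD27- CMP against MEP, 5 of 5 changed lists and 1 of 35 unchanged lists were called. The simulated noise was independent between genes, while the estimated correlation within real lists reached 0.40. The simulation therefore does not show how often the preset correlation gives false calls on real lists.

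The alternatives tried were quantile normalization, centring each array on its median, the replicate number as a block, array weights, a variance trend with robust moderation, the mean of a gene's probe sets, counts of genes, a log2 difference of at least 1, fits of the 6 compared arrays alone, an estimated inter-gene correlation and leaving out each array in turn. A filter that kept the 15263 probe sets with a range of at least 1 log2 was added after seeing the data.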

Results

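Gene expression was compared between 4 populations of lineage-negative, CD117+ and Sca-1- bone marrow progenitors from mice aged 4 to 6 weeks, with 3 arrays each. Megakaryocyte-erythrocyte progenitors (MEP) were sorted without CD34, CD16/32 or CD27, and granulocyte-monocyte progenitors (GMP) were sorted with all of them. Common myeloid progenitors (CMP), sorted with CD34 and without CD16/32, were split into a CD27+ and a CD27- fraction. CD27 is a receptor of the tumour necrosis factor receptor family. Principal components were computed over the 15263 probe sets with a range of at least 1 log2. The first of them held 77.1% of the variance and set the 6 CD27+ CMP and GMP arrays against the 6 CD27- CMP and MEP arrays. The second held 7.74%. A typical pair of arrays differed by a standard deviation (SD) of 1.66 log2 between the CMP fractions, against medians of 0.685 within CD27- CMP and 0.520 within CD27+ CMP, over probe sets with a range of at least 1 log2.

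The genes of the sort markers were read first, as a check of the labels at the level of RNA. The sort read surface proteins, which the arrays did not measure, so RNA that departs from a gate does not by itself contradict the labels. Cd34, which encodes the CD34 surface glycoprotein, had a mean centred log2 signal of 4.10 ± 0.10 in CD27+ CMP, 3.03 ± 0.15 in GMP, -3.22 ± 0.61 in CD27- CMP and -4.91 ± 1.70 in MEP (SD, n = 3). Both CMP fractions carry CD34 in their sort, yet Cd34 was lower in CD27- than in CD27+ CMP, with a log2 difference of 7.32 (SE 0.70, adjusted p = 5.1e-05). The difference of 1.69 between CD27- CMP and MEP did not pass (SE 0.70, adjusted p = 0.76). Cd27 stood at 4.10 in CD27+ CMP, 2.68 in GMP, -2.75 in CD27- CMP and -3.05 in MEP. Fcgr3 and Fcgr2b encode the Fc gamma receptors bound by the CD16/32 antibody. Fcgr3 was highest in GMP, at 7.16 ± 0.31, against 2.20 ± 1.30 in CD27+ CMP, and the 3 CD27+ CMP arrays read 3.65, 1.92 and 1.04. Fcgr2b reached 4.78 in GMP and 3.38 in CD27+ CMP, a difference that did not pass for the probe set that varied most (log2 -1.40, adjusted p = 0.062). Its other probe sets read -1.44, -1.74, -1.44 and -0.01. For every Fcgr2b probe set except the one at -0.01, all 3 GMP arrays lay above all 3 CD27+ CMP arrays. The one at -1.74 read 4.85, 4.70 and 4.79 in GMP and 3.36, 3.05 and 2.72 in CD27+ CMP. A lower Fcgr2b in CD27+ CMP is therefore not excluded. In CD27- CMP and MEP Fcgr3 read -2.51 and -1.64 and Fcgr2b -3.30 and -3.79. Both CMP fractions were sorted without CD16/32, yet Fcgr3 was higher in CD27+ than in CD27- CMP by 4.71 log2 (SE 0.60, adjusted p = 0.00034) and Fcgr2b by 6.68 (SE 0.36, adjusted p = 1.1e-06). The other Fcgr2b probe sets read 4.27, 5.90, 4.81 and -0.02 there. Kit, the gene of CD117, lay between -0.33 and 0.35 in all 4 populations and passed in no comparison. Sca-1 is encoded by Ly6a, which had no probe set with a single symbol.

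**Figure D1:**
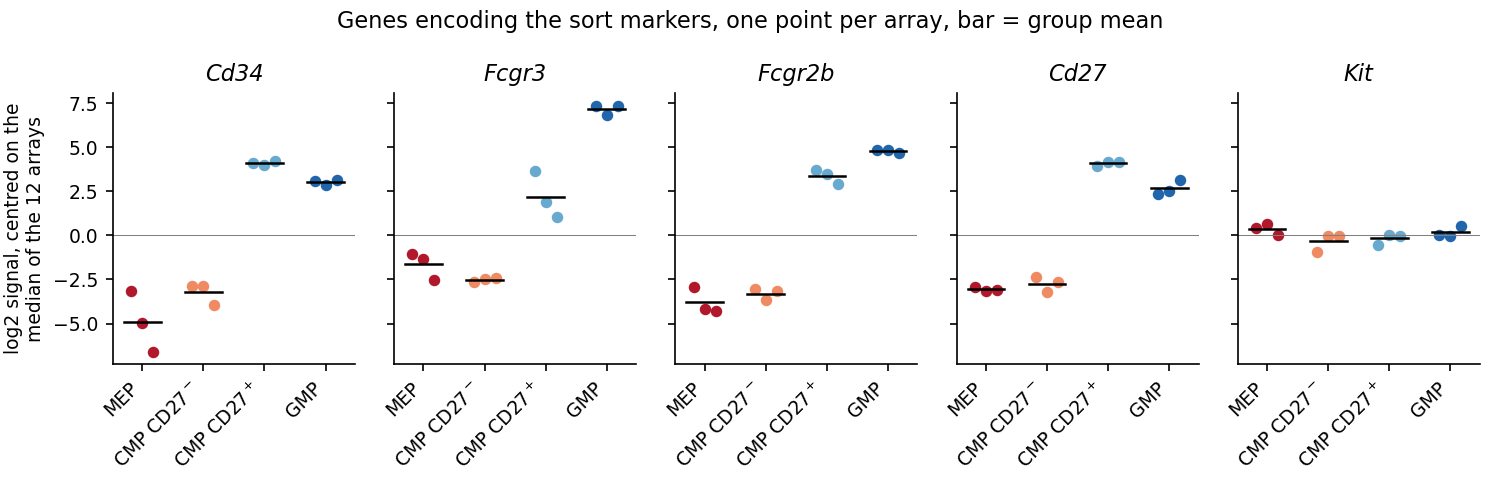
Centred log2 signal (y axis) of the genes encoding the sort markers in each population (x axis), with 1 point per array and a bar at the mean of 3 arrays. Cd34 sat at -3.22 on average in CD27- CMP and at 4.10 in CD27+ CMP, and the 3 CD27+ CMP arrays spread from 1.04 to 3.65 for Fcgr3.

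The comparison of CD27+ with CD27- CMP asked what separates the fractions of the CMP gate. Of 15 granulocyte-monocyte factor and receptor genes 14 were higher in CD27+ CMP (adjusted p = 1.2e-16 by camera, and adjusted p = 0.0093 with an estimated correlation). Of 26 erythroid genes 20 were lower (adjusted p = 2.8e-13, but adjusted p = 0.073 with an estimated correlation). The largest difference in favour of CD27+ CMP was that of Emb, encoding the adhesion molecule embigin, at 9.60 log2 (SE 0.42, adjusted p = 3.1e-07, n = 3 per group). Next came the immunoglobulin heavy chain gene Ighm (8.85), the macrophage pore protein gene Mpeg1 (8.78), Dntt (8.45), which encodes terminal deoxynucleotidyl transferase of lymphoid precursors, Ly86 (8.44) and Bex6 (8.43). The list went on with the chemokine gene Ccl9 (8.39), the tetraspanin gene Cd53 (8.32), the growth factor receptor gene Flt3 (8.28), Serpinf1 (8.13), the sphingosine 1-phosphate receptor gene S1pr3 (8.04) and Gpr171 (7.99). The adjusted p of these 12 genes was 1e-05 or lower. In the other direction stood the amino acid transporter gene Slc38a5 at -8.44 (SE 0.38, adjusted p = 3.7e-07), Cldn13 (-8.17), the nuclear lamina gene Lmna (-7.87), Tspo2 (-7.86), Atp1b2 (-7.84) and the Rh blood group gene Rhd (-7.84). They were followed by the sphingosine kinase gene Sphk1 (-7.83), Prss50 (-7.78), the blood group gene Ermap (-7.70), Rhag (-7.68), Tspan8 (-7.62) and the collagen gene Col5a1 (-7.58). For each of these 24 genes all 3 arrays of one fraction lay above all 3 of the other. These values come from the probe set that varied most, and others read less. Of 11 Ighm probe sets a second read 7.51 and the other 9 read from -0.10 to 0.00. The others of Lmna read -4.86, -1.44, -0.13 and -0.10, those of Tspan8 -2.59, -1.49, -1.16 and -0.62, and those of Col5a1 -4.04 and -0.97. A further probe set of Emb read 9.50 and another 0.50, those of S1pr3 read 4.77 and 0.02 and those of Dntt 8.40 and 4.72. The second probe set read 5.78 for Serpinf1, 3.27 for Cd53, -4.22 for Atp1b2 and -4.36 for Sphk1.

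In total 6369 probe sets changed by limma, 14.1% of those tested, with 3444 higher and 2925 lower in CD27+ CMP. The balance depended on the setting, with 4554 higher and 9183 lower under array weights and 3541 higher and 4851 lower without CD27- CMP replicate 3. By gene the numbers were 4082 of 18193, with 2206 higher and 1876 lower, and 2737 of them differed by at least 1 log2. The median size of a called difference was 1.35 log2.

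Of 26 measured erythroid genes, 20 were lower in CD27+ CMP and 0 higher, 6 did not pass, and 21 were lower when adjusted over the list alone. The median was -6.27 log2, with the erythroid master regulator Klf1 at -7.23 and the erythropoietin receptor gene Epor at -6.59. The list shifted with adjusted p = 2.8e-13 by camera and lost its call at adjusted p = 0.073 with an estimated correlation. The flat probe sets of Alas2 (0.00) and the alpha globin genes Hba-a1 (-0.02) and Hba-a2 (0.07) were among the 6. Haem synthesis genes followed, with 9 of 11 lower and 1 higher, as also when adjusted over the list alone, and a median of -1.99. Cpox was lower by the largest amount (-4.02), and the mitochondrial iron importer gene Slc25a37 was the one higher (0.83). Adjusted p was 8.1e-06, and adjusted p = 0.073 with an estimated correlation.

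Transcription factors and receptors of the granulocyte-monocyte lineage were higher in CD27+ CMP for 14 of 15 genes, over all genes and when adjusted over the list alone, with a median of 5.08. Irf8 (7.69) and Cebpa (7.13), transcription factors of monocyte and granulocyte development, and the macrophage colony-stimulating factor receptor gene Csf1r (6.92) led the list. Only Tlr4 did not pass (0.12). The list shifted with adjusted p = 1.2e-16, and adjusted p = 0.0093 with an estimated correlation. Monocyte and macrophage genes were higher for 12 of 17 (13 when adjusted over the list alone), with a median of 3.44, and the chemokine receptor gene Ccr2 stood at 7.05. Their adjusted p was 8.5e-13, and adjusted p = 0.022 with an estimated correlation. Among neutrophil granule protein genes 10 of 21 were higher, the same number when adjusted over the list alone, with a median of 1.02. Serpinb1a (6.46), Hp (6.43) and the serine protease genes Ctsg (5.58) and Elane (5.30) were among them, while the late granule genes Ltf (-0.01), Camp (-0.01) and Lcn2 (0.05) did not pass. The list had adjusted p = 2.9e-06, and adjusted p = 0.17 with an estimated correlation.

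Stem cell genes split, with 14 of 29 higher and 4 lower in CD27+ CMP, over all genes and when adjusted over the list alone, and a median of 0.60. The transcription factor genes Erg (4.24), Hlf (4.06) and Mecom (3.00) were higher, and Tgm2 (-4.96) and Mllt3 (-4.04) were lower. Adjusted p was 4.4e-05, and adjusted p = 0.022 with an estimated correlation. Of 21 early lymphoid genes 9 were higher and 1 lower, also when adjusted over the list alone, with a median of 0.51. Besides Ighm, Dntt and Flt3 these included the chromatin organizer gene Satb1 (7.24) and Notch1 (6.43), whereas the B cell factor genes Ebf1 (-0.09) and Pax5 (-0.06) did not pass. The list had adjusted p = 0.00021, and adjusted p = 0.12 with an estimated correlation. Mature B cell markers did not shift (adjusted p = 0.96), and Cd79b, a signalling chain of the B cell receptor, was the 1 of 11 that was higher (5.10). Mature T and NK cell markers did not shift either (adjusted p = 0.33, or 0.047 with the range filter), with 3 of 17 higher, namely Nkg7 (3.19), Klrd1 (2.02) and Cd28 (0.64). These counts were equal when adjusted over the list alone.

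Mast cell, basophil and eosinophil genes were higher for 5 of 19, also when adjusted over the list alone. The basophil protease gene Mcpt8 (7.18), the carboxypeptidase gene Cpa3 (6.58) and the histamine-forming Hdc (5.12) led. The median was -0.02 while the mean was 1.27 and the test pointed up, with adjusted p = 0.023, and adjusted p = 0.56 with an estimated correlation. Immediate early and stress genes were higher for 9 of 20 and lower for 1, also when adjusted over the list alone. Their median was 1.40, with Btg2 at 4.05 and Fos at 3.92 against Egr1 at -3.48, and adjusted p was 0.00034, with adjusted p = 0.11 with an estimated correlation. Ribosome biogenesis and Myc genes were lower for 10 of 22 and higher for 0, also when adjusted over the list alone. Their median was -0.45, with the polyamine synthesis gene Odc1 at -1.73 and Rrp9 at -1.56, and adjusted p was 0.0019, with adjusted p = 0.17 with an estimated correlation. Without CD27- CMP replicate 3 the adjusted p became 0.064 for the mast cell list and 0.054 for the ribosome list, and with array weights it was 0.083 for the mast cell list.

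Megakaryocyte and platelet genes went both ways, with 4 of 25 higher and 4 lower (adjusted p = 0.98). The pleckstrin gene Plek (3.56) and the platelet adhesion gene Selp (3.16) were higher, and the platelet glycoprotein gene Gp5 (-4.33) and the thrombin receptor gene F2r (-2.60) were lower. The erythro-megakaryocytic transcription factors also split, with 5 of 16 higher and 8 lower (adjusted p = 0.73). Gata1 (-5.85), Gfi1b (-4.93) and Zfpm1 (-3.90) were lower, and Mef2c (3.27), Runx1 (2.73) and Fli1 (2.69) were higher. Mitosis genes did not shift (adjusted p = 0.94), with 3 of 19 lower, Plk1 (-0.79), Cdc20 (-0.74) and Ccna2 (-0.53). DNA replication genes had 2 of 26 higher, Mcm3 (0.80) and Gins1 (0.53), and 2 lower, Ccne1 (-3.11) and Cdc6 (-0.93), with adjusted p = 0.96. Interferon response genes had 4 of 18 higher and 2 lower (adjusted p = 0.68), with Gbp3 at 3.86 and Irf7 at -1.84. Of 14 stromal and endothelial markers only Pdgfrb was higher (18.4-fold, adjusted p of the list = 0.68). Each of these counts stayed the same when adjusted over the list alone.

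**Figure D2:**
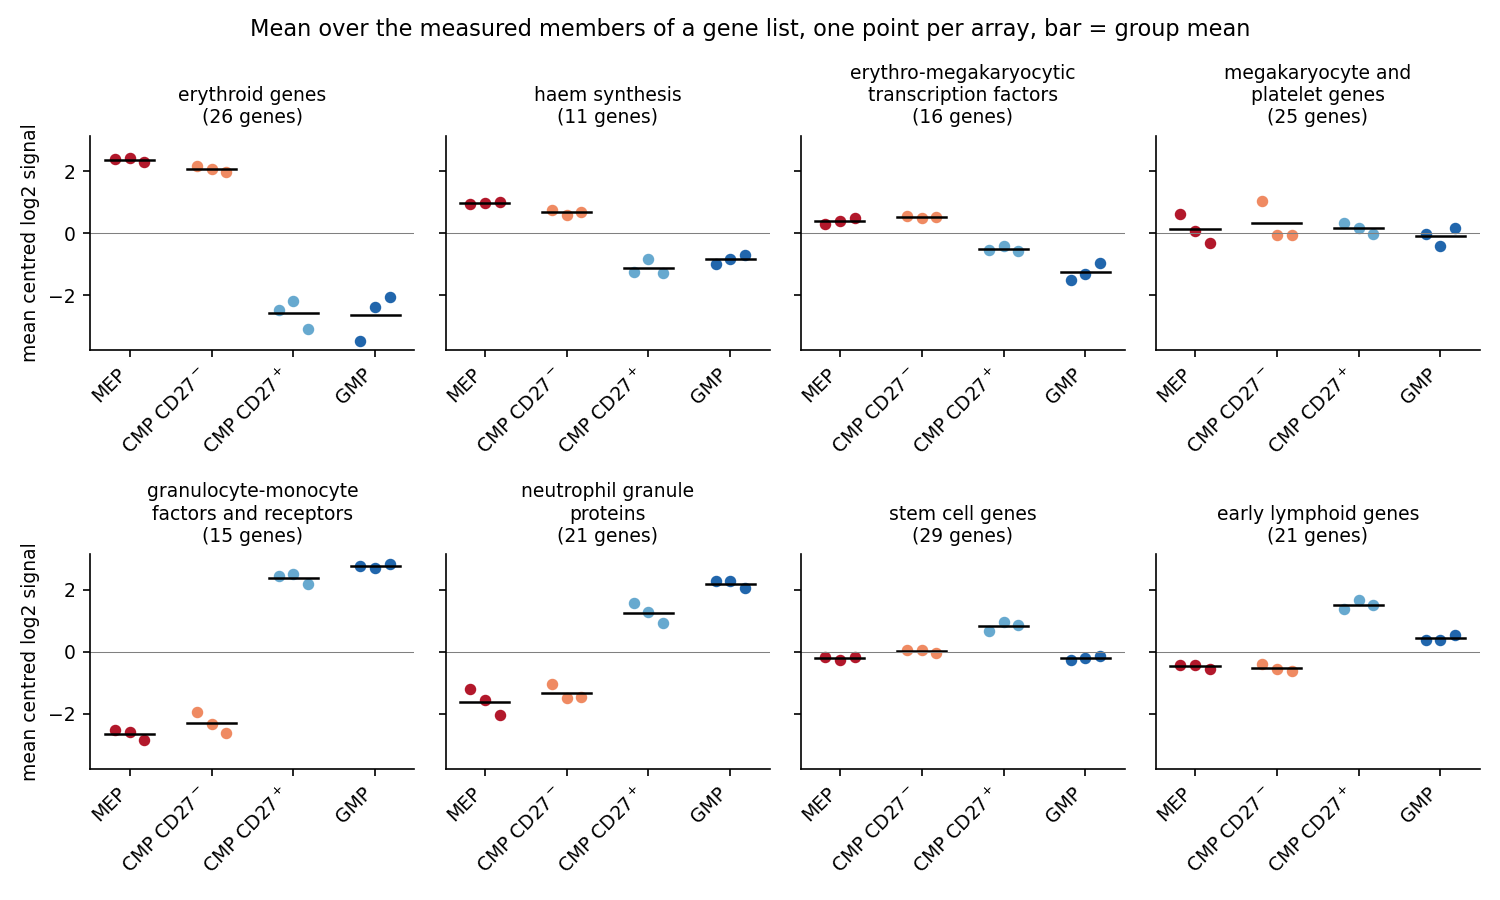
Mean centred log2 signal over the measured members of 8 gene lists (y axis) in each population (x axis), with 1 point per array and a bar at the mean of 3 arrays. Median differences between CD27+ and CD27- CMP ran from -6.27 for the 26 erythroid genes to 5.08 for the 15 granulocyte-monocyte factors and receptors.

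GMP and MEP, the committed populations, gave the reference for the lineage difference. Among the genes higher in GMP were the haptoglobin gene Hp at 9.18 log2 (SE 0.53, adjusted p = 1.5e-06, n = 3 per group), the myeloid receptor gene Trem3 (9.01), Anxa3 (8.90), Emb (8.88) and Mgst1 (8.86). Also higher were Fcgr3 (8.79), the signalling adaptor gene Tyrobp (8.67), Hdc (8.64), Fcgr2b (8.57) and Ckap4 (8.48). Higher in MEP were Lmna at -8.76 (SE 0.32, adjusted p = 8.7e-08), Cldn13 (-8.43), Rhd (-8.13), Tspan8 (-8.09), Tspo2 (-7.99), the non-muscle myosin gene Myh10 (-7.90), Col5a1 (-7.88), Slc38a5 (-7.85), Aldh1a7 (-7.81) and the Kell blood group gene Kel (-7.76). The second probe sets of Mgst1 and Myh10 read -0.03 and -0.05, and the others of Lmna ran from -5.00 to -0.02 and those of Tspan8 from -2.96 to -0.04. In total 6671 probe sets changed by limma, 14.8% of those tested, with 3395 higher and 3276 lower in GMP, a balance that turned with array weights (5362 and 12288) and with the replicate block (3412 and 3446). By gene 2094 were higher and 2064 lower.

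Granulocyte-monocyte factors and receptors were higher in GMP for 15 of 15 genes, also when adjusted over the list alone, with a median of 5.71 and Irf8 at 8.28. Adjusted p was 4.3e-21, and adjusted p = 0.0042 with an estimated correlation. Monocyte and macrophage genes were higher for 15 of 17, also when adjusted over the list alone, with a median of 3.76 and Ly86 at 8.14 (adjusted p = 4.1e-18, and adjusted p = 0.011 with an estimated correlation). Neutrophil granule protein genes were higher for 12 of 21 (13 when adjusted over the list alone), with a median of 5.35 and the granule genes Ms4a3 at 7.75 and Lcn2 at 3.32. That list had adjusted p = 1.6e-09, and adjusted p = 0.14 with an estimated correlation. Erythroid genes were lower for 20 of 26, also when adjusted over the list alone, with a median of -6.42 and Klf1 at -7.69 (adjusted p = 7.9e-13, and adjusted p = 0.12 with an estimated correlation). Haem synthesis genes were lower for 8 of 11 (9 when adjusted over the list alone) and higher for 1, with a median of -2.15 and Cpox at -3.96. Their adjusted p was 4.7e-05, and adjusted p = 0.13 with an estimated correlation. Mast cell, basophil and eosinophil genes were higher for 7 of 19 (8 when adjusted over the list alone), with Mcpt8 at 8.24 and the eosinophil granule gene Prg2 at 6.04. Their median was 0.01 and mean 2.25 (adjusted p = 0.00013, and adjusted p = 0.23 with an estimated correlation).

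Smaller shifts were those of the immediate early and stress genes, with 7 of 20 higher and 2 lower (10 and 2 when adjusted over the list alone), a median of 1.07 and Fos at 4.75. The list had adjusted p = 0.0014, and adjusted p = 0.15 with an estimated correlation. Ribosome biogenesis and Myc genes were lower for 7 of 22 (9 when adjusted over the list alone), with a median of -0.54 and Rrp9 at -1.48. They had adjusted p = 0.0039, and adjusted p = 0.22 with an estimated correlation. Stem cell genes had 9 of 29 higher and 5 lower (10 and 5 when adjusted over the list alone), with Tgm2 at -6.94, Mllt3 at -4.54 and Erg at 3.52, a median of 0.02 and a mean of 0.00. Their adjusted p of 0.042 became 0.15 under quantile normalization, 0.083 with arrays centred on their median and adjusted p = 0.15 with an estimated correlation. It also became 0.069 with the mean of probe sets and 0.43 with the range filter, and 0.066, 0.064, 0.054 and 0.072 without GMP replicate 1, GMP replicate 3, MEP replicate 1 or MEP replicate 2. The other lists did not shift. Erythro-megakaryocytic transcription factors (4 higher and 8 lower of 16, adjusted p = 0.21, or 0.037 under quantile normalization) held Gfi1b at -7.14 and Fli1 at 4.07. Megakaryocyte and platelet genes (5 higher and 3 lower of 25, adjusted p = 0.48) held F2r at -5.67 and F10 at 4.89. The rest had adjusted p of 0.12 for early lymphoid genes (4 higher, 1 lower), 0.92 for mature B cell markers (1 higher), 0.87 for mature T and NK cell markers (1 higher), 0.44 for mitosis (4 lower, 5 when adjusted over the list alone), 0.35 for DNA replication (1 higher, 4 lower), 0.88 for interferon response (1 higher, 4 lower) and 0.88 for stromal and endothelial markers (2 higher).

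The split of CMP by CD27 was then set against the difference between GMP and MEP, in a pair of fits that shared no array. Between the CMP fractions 1891 genes passed higher and 1468 lower, and between GMP and MEP 1983 and 1897. Of 2466 genes past the threshold in both, 2463 (99.88%) had the same sign. Genes past the threshold in a single comparison do not enter this share. Genes higher in both CD27+ CMP and GMP numbered 1390, against 206 under independence, and 1073 were lower in both, against 153. The log2 differences correlated with r = 0.91 across the 18193 genes, which are not independent replicates. The 3 genes with opposite signs were Gimap6 (1.48 between the CMP fractions and -2.26 between GMP and MEP), a GTPase gene of the immunity-associated family, Mn1 (1.15 and -0.42) and Smpdl3a (-0.69 and 0.54). They were named after their values were seen, because they are so few.

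**Figure D3:**
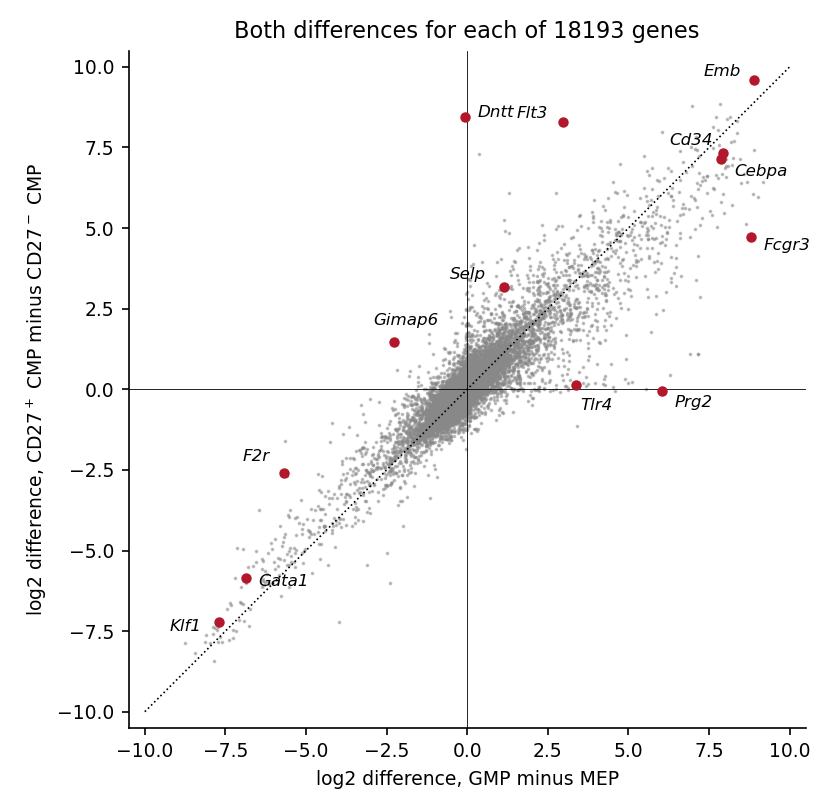
Log2 difference of CD27+ minus CD27- CMP (y axis) against GMP minus MEP (x axis) for each of 18193 genes, with named genes in red and a dotted line of equal differences. Most large differences lie along the line, while Dntt (8.45 and -0.07) and Prg2 (-0.04 and 6.04) lie on the axes.

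On the position score, with MEP at 0 and GMP at 100, CD27- CMP stood at 6.77 ± 0.651 and CD27+ CMP at 92.5 ± 3.41 (SD, n = 3). The score rested on 1983 genes higher in GMP and 1897 higher in MEP. The CMP fractions differed by 85.7 (exact two-sided permutation p = 0.1, the smallest possible with 3 arrays against 3). CD27- CMP lay 6.77 above MEP and CD27+ CMP lay 7.55 below GMP, but the GMP and MEP arrays had chosen the genes of the score and the CMP arrays had not. In a test added after these values were seen, each GMP and MEP array was scored on genes chosen and scaled without it. Held-out MEP arrays then averaged 2.36 (-0.737 to 5.47) against 7.72 for CD27- CMP (6.99 to 8.22). Held-out GMP arrays averaged 97.6 (94 to 105) against 91.5 for CD27+ CMP (88.1 to 95), with overlapping ranges. Scored on the GMP-high genes alone, CD27- CMP stood at 4.12 and CD27+ CMP at 90.3. Scored on the MEP-high genes alone, they stood at 10.7 and 95.7.

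**Figure D4:**
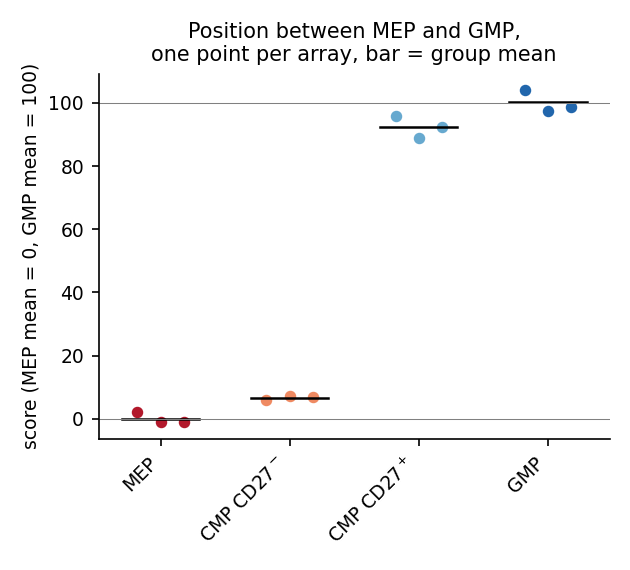
Position score (y axis, with the MEP mean at 0 and the GMP mean at 100) in each population (x axis), with 1 point per array and a bar at the mean of 3 arrays. The CD27- CMP arrays averaged 6.77 and the CD27+ CMP arrays 92.5.

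CD27+ CMP and GMP, which share CD34 and CD27 and differ in CD16/32, were compared next. Dntt was higher in CD27+ CMP by 8.52 log2 (SE 0.18, adjusted p = 1.6e-08, n = 3 per group), followed by Wfdc17 (6.92), Flt3 (5.41), the potassium channel gene Kcng1 (4.83), Cox6a2 (4.27), Epb41l4b (4.27), Gimap6 (4.09) and F2r (3.77). Higher in GMP were the sphingomyelin synthase gene Sgms2 at -6.24 (SE 0.56, adjusted p = 0.00027), Prg2 (-6.23), the cortisone-reducing enzyme gene Hsd11b1 (-6.10), Prom1 (-5.91), Chst13 (-5.83), the guanine deaminase gene Gda (-5.38), Fcgr3 (-4.95) and the adhesion molecule gene Vcam1 (-4.89). Further probe sets read 4.73 for Dntt, 1.86 for Cox6a2, -0.02 for Kcng1, -0.02 and 0.00 for Epb41l4b, 0.00 for Gimap6, -2.19 for Sgms2 and -0.80 and -0.09 for Vcam1. In total 1368 probe sets changed by limma, 3.04% of those tested, with 662 higher and 706 lower in CD27+ CMP, and by gene 471 were higher and 483 lower. The balance turned without CD27+ CMP replicate 1 (624 higher and 550 lower) or 3 (533 and 451), at a log2 difference of at least 1 (460 and 447) and with the range filter (832 and 828). Without GMP replicate 2 the count was 898 probe sets, and with only the 6 compared arrays it was 600. In that fit the adjusted p of Gda (0.076), Hsd11b1 (0.061), Prg2 (0.051) and Prom1 (0.060) no longer passed.

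Stem cell genes were higher in CD27+ CMP than in GMP for 10 of 29 (17 when adjusted over the list alone) and lower for 0, with a median of 0.68. The transcription factor genes Mycn (3.05) and Mecom (2.48) and the TIE2 ligand gene Angpt1 (2.73) led the list, with adjusted p = 3e-17, and adjusted p = 0.00056 with an estimated correlation. Erythro-megakaryocytic transcription factors were higher for 5 of 16 (8 when adjusted over the list alone), namely Gfi1b (2.25), the GATA1 cofactor gene Zfpm1 (2.02), Gata2 (1.19), Cbfa2t3 (0.92) and Lmo2 (0.57). Their adjusted p was 1.7e-06, and adjusted p = 0.0097 with an estimated correlation. Early lymphoid genes were higher for 6 of 21 (8 when adjusted over the list alone), with Satb1 at 1.89, the recombinase gene Rag2 at 0.89 and the interleukin 7 receptor gene Il7r at 0.51. This list had adjusted p = 1.5e-08, and adjusted p = 0.043 with an estimated correlation. Neutrophil granule protein genes were lower in CD27+ CMP for 5 of 21 (6 when adjusted over the list alone), with S100a8 at -4.56 and Lcn2 at -3.31, and with adjusted p = 0.00042, or adjusted p = 0.43 with an estimated correlation. Mast cell, basophil and eosinophil genes were lower for 5 of 19 (7 when adjusted over the list alone), with Hdc at -3.24 and Prg3 at -3.19. Their median was -0.01 and mean -0.91 (adjusted p = 5.5e-05, and adjusted p = 0.29 with an estimated correlation).

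Interferon response genes were higher in CD27+ CMP for 2 of 18, Rtp4 (2.59) and Usp18 (1.83), or 6 when adjusted over the list alone, with adjusted p = 0.00074, and adjusted p = 0.095 with an estimated correlation. Immediate early and stress genes were higher for 2 of 20, Dusp2 (1.06) and Klf6 (0.78), or 5 when adjusted over the list alone, with adjusted p = 0.0027, and adjusted p = 0.22 with an estimated correlation. Monocyte and macrophage genes had 2 of 17 higher (3 when adjusted over the list alone) and 5 lower, with the endotoxin coreceptor gene Cd14 at -3.41. Their median was 0.04 and mean -0.41 (adjusted p = 0.30). Granulocyte-monocyte factors and receptors had 2 of 15 lower, Tlr4 (-3.29) and Gfi1 (-2.04), or 1 higher and 6 lower when adjusted over the list alone, with adjusted p = 0.11, or 0.022 without GMP replicate 2. Erythroid genes had 0 of 26 past the threshold by limma, against 3 at an unadjusted p under 0.05 (adjusted p = 0.43, or 0.043 without GMP replicate 3), and Tfrc stood at -1.80 and Car2 at 1.64. Haem synthesis genes had 1 of 11 lower, Abcb10 (-1.51), with adjusted p = 0.11. That p became 0.039 with the mean of probe sets, 0.032 under quantile normalization, 0.0029 without CD27+ CMP replicate 2 and 0.045 without GMP replicate 1. Megakaryocyte and platelet genes had 3 of 25 higher, led by F2r, and 2 lower, F10 (-3.55) and F5 (-1.81), with adjusted p = 0.30. The remaining lists had adjusted p of 0.43 for mature B cell markers (0 of 11, 1 at an unadjusted p under 0.05), 0.65 for mature T and NK cell markers (2 higher, 1 lower), 0.43 for mitosis (0 of 19, also 0 unadjusted), 0.52 for DNA replication (2 lower), 0.43 for ribosome biogenesis and Myc (0 of 22, also 0 unadjusted) and 0.89 for stromal and endothelial markers (1 higher, 1 lower).

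CD27- CMP and MEP differ in CD34 by their sort. The number of genes that separated them depended on the setting. The actin motor gene Myo1g was higher in CD27- CMP by 1.71 log2 (SE 0.18, adjusted p = 0.019, n = 3 per group), the signalling adaptor gene Lcp2 by 1.23 (SE 0.12, adjusted p = 0.013) and the transcription factor gene Fli1 by 1.10 (SE 0.12, adjusted p = 0.021). Lower were the fatty acid desaturase gene Scd1 at -2.84 (SE 0.23, adjusted p = 0.0055), Efr3a at -1.13 (SE 0.11, adjusted p = 0.012) and Rom1 at -0.75 (SE 0.043, adjusted p = 0.00055). The second probe set of Scd1 read -0.77 and that of Lcp2 -0.03, and the others of Efr3a read -0.06 and -0.27. In total 20 probe sets passed by limma, 5 higher and 15 lower, 0.0444% of those tested, against 2435 at an unadjusted p under 0.05. By gene the numbers were 3 and 3. Array weights gave 3820 probe sets, and a variance trend with robust moderation gave 2. Without CD27- CMP replicate 3, 1 or 2 the probe set counts were 161 (71 higher and 90 lower), 62 (33 and 29) and 34 (17 and 17). Without MEP replicate 3, 1 or 2 they were 85 (12 and 73), 47 (12 and 35) and 26 (4 and 22), and the range filter gave 28 (15 and 13). In a fit of the 6 compared arrays alone limma called 0 probe sets, with 1841 at an unadjusted p under 0.05. The calls of Myo1g, Lcp2, Fli1 and Efr3a were lost without MEP replicate 2 (adjusted p = 0.051, 0.066, 0.082 and 0.058), and that of Myo1g also without CD27- CMP replicate 2 (adjusted p = 0.056). Array SDs of difference between CD27- CMP and MEP ran from 0.557 to 0.719 log2 (median 0.592), those within CD27- CMP from 0.528 to 0.825 (median 0.685) and those within MEP from 0.369 to 0.627 (median 0.498).

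Among the members of the gene lists only Fli1 passed in CD27- CMP against MEP, and counts adjusted over the list alone were at most 2. By camera 10 lists were called with the preset correlation, 8 pointing up and 2 down, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Stem cell genes had adjusted p = 0.00032 (median 0.11, adjusted p = 0.063 with an estimated correlation), with Mycn at 2.25 and Meis1 at 1.18. Megakaryocyte and platelet genes had adjusted p = 0.00032 (median 0.25, adjusted p = 0.35 with an estimated correlation), and pointed up, although their largest differences went both ways, with Ppbp at -1.89, Tubb1 at -1.86, Pf4 at 1.32 and Itga2b at 1.21, none of which passed. Monocyte and macrophage genes (median 0.05) and granulocyte-monocyte factors and receptors (median 0.11) each had adjusted p = 0.0023, and adjusted p = 0.24 with an estimated correlation, with F13a1 at 1.54 and Csf1r at 1.74. Erythro-megakaryocytic transcription factors had adjusted p = 0.0028 (median 0.05, adjusted p = 0.10 with an estimated correlation), and haem synthesis genes pointed down with adjusted p = 0.0052 (median -0.25, adjusted p = 0.24 with an estimated correlation). DNA replication genes also pointed down with adjusted p = 0.0065 (median -0.15, adjusted p = 0.24 with an estimated correlation). Neutrophil granule protein genes had adjusted p = 0.0087 (median 0.05, adjusted p = 0.47 with an estimated correlation) and interferon response genes 0.012 (median 0.12, adjusted p = 0.24 with an estimated correlation). Immediate early and stress genes had adjusted p = 0.028, a median of -0.02 and a mean of 0.10 (adjusted p = 0.34 with an estimated correlation). Not called, with the adjusted p in parentheses, were erythroid genes (0.21, or 0.041 and pointing down with the range filter), early lymphoid genes (0.31), mature B cell markers (0.11), mature T and NK cell markers (0.96), mast cell, basophil and eosinophil genes (0.36), mitosis (0.62), ribosome biogenesis and Myc (0.36) and stromal and endothelial markers (0.36). The number of called lists was 5 without CD27- CMP replicate 1 or MEP replicate 3, 4 with array weights and 4 under quantile normalization. Array weights ended the calls of DNA replication (0.21), erythro-megakaryocytic factors (0.12), granulocyte-monocyte factors (0.23), immediate early (0.39), megakaryocyte (0.086) and granule protein genes (0.24). Quantile normalization ended those of erythro-megakaryocytic factors (0.084), granulocyte-monocyte factors (0.93), immediate early (0.13), interferon response (0.13), monocyte (0.48) and granule protein genes (0.53). Immediate early and interferon response genes also lost theirs with centred arrays (0.083 and 0.074) and with the range filter (0.072 and 0.14). Without CD27- CMP replicate 1 the calls of DNA replication (0.15), granulocyte-monocyte factors (0.058), immediate early (0.34), megakaryocyte (0.098) and granule protein genes (0.098) ended. Those of haem synthesis (0.056) and interferon response (0.087) ended without CD27- CMP replicate 2, where mature B cell markers were called (0.047). Without CD27- CMP replicate 3 the calls of erythro-megakaryocytic factors (0.076), immediate early (0.072), interferon response (0.15) and granule protein genes (0.081) ended and mitosis was called (0.031). Without MEP replicate 3 those of DNA replication (0.22), haem synthesis (0.085), immediate early (0.097), megakaryocyte (0.061) and granule protein genes (0.40) ended, without MEP replicate 2 that of interferon response (0.075), and without MEP replicate 1 ribosome biogenesis was called (0.043).

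The remaining comparisons set each CMP fraction against the committed population of the other side. In CD27+ CMP against MEP the largest differences were those of Emb (9.33, SE 0.42, adjusted p = 3.3e-07), Irf8 (9.31), the lymphocyte surface antigen gene Cd52 (9.02) and Cd34 (9.01), and, lower, Cldn13 (-8.58), Slc38a5 (-8.48), Tspan8 (-8.26) and Rhd (-8.22). By limma 7210 probe sets changed, 3453 higher and 3757 lower. This balance turned with centred arrays (3531 and 3278), under quantile normalization (4046 and 3272) and with a log2 difference of at least 1 (2628 and 2022). It also turned without CD27+ CMP replicate 1 (3148 and 2778) or 3 (3155 and 2765) or MEP replicate 2 (2910 and 2907). In CD27- CMP against GMP the largest were Lmna (8.42, SE 0.32, adjusted p = 1.3e-07), Cldn13 (8.02), Col5a1 (7.82) and Slc38a5 (7.81), and, lower, Fcgr3 (-9.67), Emb (-9.15), Hp (-8.98) and the choline dehydrogenase gene Chdh (-8.88). There 6393 probe sets changed, 2837 higher and 3556 lower, which turned with array weights (7623 and 4805) and without CD27- CMP replicate 3 (4252 and 3640).

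Genes higher in one population than in each of the other 3 numbered 341 in CD27+ CMP, 359 in GMP, 2 in MEP and 0 in CD27- CMP by limma, and 97 in CD27- CMP at unadjusted p under 0.05 in all 3 contrasts. Their smallest of 3 log2 differences was 8.45 for Dntt, 6.92 for Wfdc17, 5.41 for Flt3, 4.83 for Kcng1 and 4.27 for Cox6a2 and Epb41l4b in CD27+ CMP. In GMP it was 6.24 for Sgms2, 6.10 for Hsd11b1, 6.04 for Prg2, 5.91 for Prom1, 5.83 for Chst13 and 4.95 for Fcgr3. The genes of MEP were Scd1 (2.84) and Rom1 (0.75). Left-out arrays moved both small counts. Genes highest in MEP numbered 8 and 20 without CD27- CMP replicates 1 and 3, 5 without CD27+ CMP replicate 2, and 16, 4 and 18 without MEP replicates 1, 2 and 3. Genes highest in CD27- CMP numbered 9, 4 and 13 without its replicates 1, 2 and 3 and 1 without CD27+ CMP replicate 3. With array weights the counts were 683 for MEP and 428 for CD27- CMP.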

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

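The alternatives were fixed in advance except the filter on range, the held-out position scores, the estimated correlation in other splits and the gene-by-gene estimator of array weights, chosen because the default one did not converge (its weights ran from 1.65e-07 to 52.2). Testing all probe sets and taking the probe set with the largest SD per gene were set after the values were seen to be centred. None of the 82 named gene results reversed, nor did a called list among the 72 list results or the position difference. The rest of the 16 main results are counts and a share, which could only be judged as kept or moved. The balance of higher and lower probe sets turned in several settings, as given above. Centring each array on its median and the filter on range left all 16 main results on their side or within 1.5 times. Named genes kept their call in 82 of 82 results with array weights and with centred arrays, and in 72 of 82 with only the 6 compared arrays. For 72 list results 28 calls were lost with an estimated correlation. The causes were not tested unless named. For comparisons in the order CD27+ against CD27- CMP, GMP against MEP, CD27+ CMP against GMP, CD27- CMP against MEP, CD27+ CMP against MEP and CD27- CMP against GMP, array weights gave 13737, 17650, 2533, 3820, 27715 and 12428 probe sets. With array weights MEP replicate 2 had a weight of 11.1 and CD27- CMP replicate 3 of 0.184. A log2 difference of at least 1, which removes small calls by construction, gave 4150, 4382, 907, 11, 4650 and 4234. Genes in place of probe sets, fewer by construction, gave 4082, 4158, 6, 4515 and 4059 without CD27+ CMP against GMP, where the count kept within 1.5 times. Only the 6 compared arrays, with fewer residual degrees of freedom, gave 600 for CD27+ CMP against GMP and 0 for CD27- CMP against MEP. A variance trend with robust moderation gave 2 for the latter. Array weights gave 428 genes highest in CD27- CMP, 512 in CD27+ CMP, 606 in GMP and 683 in MEP. Genes highest in MEP were 1 with the variance trend, 1 with the log2 difference, 4 with the mean of probe sets and 5 under quantile normalization. Lists called with an estimated correlation were 3, 2, 3 and 0 for the first 4 comparisons, and for CD27- CMP against MEP 4 with array weights and 4 under quantile normalization. The position difference was 88.8 under quantile normalization. The same-direction share was 99.04% with array weights and 99.61% with the replicate block.

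Leaving out each array in turn gave 5180 to 8392 probe sets for CD27+ against CD27- CMP, 5326 to 6270 for GMP against MEP, 898 to 1419 for CD27+ CMP against GMP, 26 to 161 for CD27- CMP against MEP, 5817 to 6704 for CD27+ CMP against MEP and 5079 to 7892 for CD27- CMP against GMP. Called lists ran from 8 to 10, 8 to 9, 7 to 8 and 5 to 11 in the first 4. Genes highest ran from 237 to 342 in CD27+ CMP, 246 to 363 in GMP, 2 to 20 in MEP and 0 to 13 in CD27- CMP. The position difference ran from 83.7 to 87.4 and the same-direction share from 99.66% to 99.95%. In the comparisons whose numbers pair the arrays the block changed no named gene or list call, and gave 6858 probe sets for GMP against MEP, 6229 of them shared with the 6671, and 1356 for CD27+ CMP against GMP, 1149 of them shared with the 1368. Elsewhere same-numbered arrays correlated from -0.33 to 0.40, and not every array matched its own number best. Among the GMP arrays, CD27+ CMP replicate 2 did not match its own number best either, although the rule was met. The block ended the calls of Fli1 (adjusted p = 0.072), Lcp2 (0.070) and Myo1g (0.072) in CD27- CMP against MEP. Other settings ended calls there too: the mean of probe sets those of Efr3a, Fli1 and Scd1, quantile normalization those of Fli1 and Myo1g, only the 6 compared arrays those of all 6 named genes, and the variance trend those of Myo1g, Lcp2, Fli1, Efr3a and Rom1. Signal over background is unknown in centred values, so neither a dim filter nor a stricter one was run.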

Other observations

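The tests of a duplicate library, of the Cd34 probe set and of the same cells under both labels were chosen only after the result was seen. So were those of B, T and NK cells, with the bounds of all these tests. The gene families named here and the correction of a sign in the test of a shared difference also came after it. The tests of mature B, T and NK cells were revised after their values were seen. Their verdict went against these cells, then was open under a rule for flat markers, and then went against them again. Below, these cells are argued against only as a source that raised all its markers. They stay open otherwise, since most of these markers are flat. The verdict on B cell precursors went from one against them to open. Families of at least 10 genes with a shared symbol stem, 225 in all, were tested with limma's camera, and the calls named here all ended with an estimated correlation. In CD27+ against CD27- CMP, 11 of 29 mitochondrial ribosomal Mrps genes were lower and 0 higher (median -0.59, adjusted p = 0.00069, or adjusted p = 0.99 with an estimated correlation). Of 47 Mrpl genes 16 were lower and 0 higher (median -0.53, adjusted p = 0.0011, or adjusted p = 1 with an estimated correlation). Mitochondrial import genes of the Timm family were lower for 7 of 15 (median -0.56, adjusted p = 0.0065, or 0.60 with an estimated correlation). RNA polymerase subunit genes of the Polr family were lower for 11 of 25 and higher for 1 (median -0.51, adjusted p = 0.015, or 0.99 with an estimated correlation). Higher in CD27+ CMP were 5 of 10 genes of Dock guanine nucleotide exchange factors (median 1.10, adjusted p = 0.014, or 0.32 with an estimated correlation) and 6 of 11 annexin genes, with 1 lower (median 1.42, adjusted p = 0.026, or 0.33 with an estimated correlation). Of interferon regulatory factor genes 6 of 11 were higher and 1 lower (median 0.71, adjusted p = 0.042, or 0.51 with an estimated correlation and 0.068 under quantile normalization). These directions kept their sign under quantile normalization and with centred arrays. In GMP against MEP 13 of 29 Mrps genes and 22 of 47 Mrpl genes were lower and 1 Mrpl gene was higher (adjusted p = 0.0088 for both families, or adjusted p = 0.99 with an estimated correlation), and 7 of 10 Dock genes were higher (median 1.65, adjusted p = 0.00054, or adjusted p = 0.24 with an estimated correlation).

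CD27- CMP arrays read like MEP arrays, Cd34 included, although their sort required CD34. The sort read surface protein and the arrays RNA, and whether Cd34 RNA followed CD34 protein in these cells was not tested. A library deposited under both labels is argued against, since the closest CD27- CMP and MEP arrays differed by an SD of 0.557 log2, above the 0.369 of the closest replicates. A Cd34 probe set that does not respond is argued against by its difference of 7.32 (SE 0.70) between the CMP fractions. The same cells under both labels, for example through overlapping CD34 gates, stay open: CD27- CMP exceeded MEP arrays scored on genes chosen without them by 5.36, but the gap of 1.52 between the lowest CD27- CMP and the highest MEP array was below the larger SD of 3.10. CD27- CMP cells that are committed to the MEP lineage remain a biological explanation that these data may fit but do not test.

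Fcgr3 was higher in CD27+ CMP replicate 1 (3.65) than in replicates 2 and 3 (1.92 and 1.04). GMP cells within that array could be the source, although the sort excluded CD16/32+ cells. Over 67 genes at least 8-fold higher in GMP than in replicate 3, replicate 1 exceeded replicate 2 by a median of 0.48 log2 (quartiles 0.06 and 1.16), and 53 of 67 (79.1%) were higher. The median fell between the bounds set in advance, so GMP cells stay open. A gradient of maturation within the CMP gate was not tested.

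Dntt, Ighm and Cd79b were higher in CD27+ than in CD27- CMP. One B lineage source of all 3 genes in the CD27+ CMP and GMP sorts is argued against, since Dntt minus Cd79b differed by 8.30 log2 (SE 0.27) between these populations, while a source of Dntt alone is not excluded. Mature B cells and T or NK cells are argued against as a source that raised all its markers by as much as these genes. Their markers had medians of -0.03 over 11 markers (quartiles -0.16 and 0.06) and -0.01 over 17 markers (quartiles -0.03 and 0.00). These lie below 5.10, the smallest of the 3 differences. However, 7 of the 11 and 13 of the 17 markers were flat, with a range under 0.5, and 1 of the 11 and 3 of the 17 were called higher. Nothing can be said about the level of a flat probe set, so such cells stay open as a source that raised only some of its markers. B cell precursors stay open, although the sort kept only lineage-negative, CD117+ and Sca-1- cells, since their stages need not carry all 21 early lymphoid genes. These genes had a median of 0.51 (quartiles -0.06 and 0.97), with 9 higher, Rag2 (0.97) and Il7r (0.51) among them, and 1 lower. The B cell factor genes Ebf1 and Pax5 did not pass. Early lymphoid transcripts within CD27+ CMP themselves may account for the pattern, as a hypothesis found on these data and not tested.

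A difference shared by both CMP fractions was put forward as a hypothesis before its result was seen. Of 491 genes past the threshold in a fit of the CD27+ CMP and GMP arrays, 63.7% had the same sign in CD27- CMP minus MEP, against at most 59.5% in the other 9 splits of those 6 arrays or their mirrors. The log2 differences correlated with r = 0.28 across these genes, which are not independent. A first calculation had turned the sign of the real split and gave the complement, 36.3%, and the correction was made after that value was seen. It also changed the count of same-direction genes given below. The corrected value lies above the 60% set in advance, so both CMP fractions may share part of what separates CD27+ CMP from GMP. The splits cannot decide this, since 10 are too few for a share under 0.05. The mixed ones also keep part of the real difference, so 59.5% is not the level without any difference.

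Other splits of the arrays were fitted for every count. Each pair of groups allows 10 splits, too few for a share under 0.05. The real split gave 6369 probe sets for CD27+ against CD27- CMP (highest other 2), 6671 for GMP against MEP (0), 1368 for CD27+ CMP against GMP (5), 20 for CD27- CMP against MEP (5), 7210 for CD27+ CMP against MEP (0) and 6393 for CD27- CMP against GMP (2), and in each case 1 of 10 splits, the real one, gave as many. Genes past both thresholds in the same direction were 2463 (highest other 0, 1 of 10). Called lists were 10 in CD27+ against CD27- CMP (highest other 10, 2 of 10 splits), 9 in GMP against MEP (10, 4 of 10), 7 in CD27+ CMP against GMP (8, 3 of 10) and 10 in CD27- CMP against MEP (6, 1 of 10). In the first 3 of these comparisons camera with the preset correlation thus called as many lists in some mixed splits, where at most 5 probe sets passed. With an estimated correlation the real split gave 3, 2, 3 and 0 lists and the mixed splits at most 0. The calls in mixed splits therefore depended on the preset correlation, and no further cause was tested. Each side of a mixed split still holds more arrays of one group than of the other, so part of the real difference remains. Mixed splits thus do not show how many lists would be called without any difference, and their calls need not be false. In 100 regroupings of the 12 arrays, the real one included, 1 of 100 gave as many genes highest in CD27+ CMP (341, highest other 127). For GMP it was also 1 of 100 (359, highest other 2). Most regroupings mix CD27+ CMP or GMP arrays with CD27- CMP or MEP arrays, which raises the spread within groups. They thus do not test CD27+ CMP against GMP, where 10 splits are too few, so chance is not excluded for these counts. For MEP 5 of 100 gave as many as 2 (highest other 119), so chance cannot be excluded. For CD27- CMP the count was 0, which all 100 of 100 reach by construction (highest other 115), so nothing was tested.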
